A study of Mus musculus with 9 samples.

How the data were processed

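RNA of TtT/GF cells, a mouse cell line of pituitary folliculostellate cells, was measured on 9 Affymetrix MG_U74A v2 GeneChips, 1 per culture. The labels put the arrays in 3 groups of 3: untreated cells, cells given 10 µM NECA for 30 min and cells given it for 120 min. NECA (5'-N-ethylcarboxamidoadenosine) is an adenosine analog that activates adenosine receptors. The cells were kept in medium with heat-inactivated serum, RNA was extracted with TriZol and biotin-labelled cRNA was hybridised, per the labels' protocols. Each treated sample's group was taken from its title and each untreated sample's from its agent label.

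The deposited table holds 1 intensity per probe set and array on a linear scale, named as MAS5 in the submitters' processing notes, with a version not given in the sources used here. In general, MAS5 subtracts the local background, combines the probes of a set and scales each array to a common trimmed mean. In the deposited values the 2% trimmed mean lay between 100.056 and 100.065 on all 9 arrays, so the values were used as the authors scaled them. The MAS5 detection calls were not used here.

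The table holds 12488 probe sets. Of these, 66 control probe sets were used only for checks of array quality. Among the other 12422, GEO's platform annotation gives 1 gene symbol for 10833, several for 396 and none for 1193. The gene IDs of 10817 probe sets were found in the reference gene table, and no symbol had to be updated. Probe annotation of this array design can be old. Probe sets with several symbols or none were tested and counted but not named.

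Signals were turned into log2(signal + 7.93), where the offset is the 25th percentile of all values. Folds on that scale understate the change of genes whose signal is near the offset. A probe set was tested if its signal was above 20.5, the 40th percentile of all values, in at least 3 of the 9 arrays. The filter kept 7851 probe sets for 5897 named genes and left out 4571. Tests used limma 3.58.1 in R 4.3.3, with lmFit on all 9 arrays and eBayes with an intensity trend in the prior variance. The contrasts were 30 min against untreated, 120 min against untreated and 120 min against 30 min, and a moderated F-test covered the 3 groups together. All tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the tested probe sets of each contrast, with a threshold of 0.05. The prior had 5.68 degrees of freedom, the median residual SD was 0.21 and the median standard error of a change was 0.18, both on the log2 scale. Values of single arrays, such as control ratios, were compared with two-sided exact permutation tests.

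The gene lists, the tests and the rule for named genes were fixed before the data were examined. In each comparison with untreated cells the rule names the 10 largest rises and the 10 largest falls among named genes that passed the test and whose treated arrays all lay on one side of all untreated arrays. In the comparison of the 2 times it names the 5 largest of each. Where fewer than 5 pass in a direction, it gives the 5 genes with the smallest p in that direction as values. Up to 4 members of each list with the smallest p are named, and Nr4a1, Il6, Vegfa, Gja1 and Adora2b always. Each gene is represented by the probe set with the highest mean over all arrays.

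The 25 gene lists hold 509 genes, of which 417 are on the array. They cover immediate early transcription factors, cAMP and CREB target genes, MAP kinase phosphatases and feedback inhibitors, cytokines and chemokines, NF-kB target and feedback genes, JAK-STAT signalling and feedback genes, adenosine receptors and adenosine metabolism, growth and angiogenic factors, and folliculostellate markers and gap junction genes. Others cover glucocorticoid-responsive genes, heat shock proteins, the unfolded protein and integrated stress response, the oxidative stress and DNA damage response, SRF targets and the actin cytoskeleton, cyclins and cell cycle, cholesterol synthesis and uptake, and glycolysis and hypoxia response. The rest are extracellular matrix and proteases, prostaglandin and nitric oxide synthesis, circadian clock genes, cytosolic ribosomal proteins, the mitochondrial respiratory chain, and markers of pituitary hormone cells, endothelial cells, and macrophages and leukocytes. Lists with at least 5 tested members were tested with camera (preset correlation of 0.01, adjusted over the 24 lists), again with a correlation estimated per list, and with fry. Members that passed were counted over all tested probe sets and also adjusted over the list alone.

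The test was checked on simulated values with the means and spread of the real probe sets. For 30 min against untreated, 16% of 50 simulated changes of 0.5, 82% of those of 1, and 100% of those of 2 and of 3 on the log2 scale were recovered among 7851 probe sets, with 10 calls among the 7651 unchanged. For 120 min against untreated the shares were 12%, 86%, 98% and 100%, with 3 calls among the unchanged. A simulated shift of 0.5 in 1 list at 120 min gave an adjusted p of 6.78e-14, and 0 of the other lists were called. The simulated values were drawn independently for each probe set and array. These checks therefore do not show how often false calls arise with correlated genes or with structure among the arrays.

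The alternatives tried were quantile normalization, other offsets, no filter and a stricter filter, no intensity trend, the replicate number as a block, only the compared groups in the fit, 1 probe set per gene, each array left out, and the other set tests. Chosen after seeing the data were the Gapdh 3' to 5' signal ratio as a covariate, only probe sets with plain names, and the cAMP list without genes of the immediate early list. The correlation of the changes at 30 and 120 min was set against 100 simulated pairs of unchanged groups that share 3 control arrays. No array was left out.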

Results

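Gene expression was measured with arrays in TtT/GF cells, a mouse pituitary folliculostellate cell line, left untreated or given 10 µM of the adenosine analog NECA for 30 or 120 min. Folliculostellate cells are the non-hormonal, gap junction-coupled cells of the anterior pituitary. Each group had 3 arrays, from replicate cultures according to the submitters' design. The labels name no vehicle and no time for the untreated cells, so no time-matched control was compared. Effects of handling or of a change of medium therefore cannot be told apart from those of NECA at either time. The number of arrays limits the precision, and an exact permutation test of 3 against 3 cannot go below p = 0.1. Detection calls were not used here, so for the lowest signals the log2(signal + offset) scale understates the fold. Genes were named by rules fixed before the data were examined.

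Arrays of a group resembled each other, with correlations across probe sets of 0.974 to 0.978 for untreated, 0.947 to 0.969 for 30 min and 0.967 to 0.972 for 120 min. Genes are not independent replicates, so these carry no p. The median signal was 37.4 ± 1.05 in untreated, 34.6 ± 0.96 at 30 min and 34.5 ± 1.56 at 120 min (SD, n = 3 each), with an exact permutation p of 0.1 for each treated group. The Gapdh 3' to 5' signal ratio, a sign of RNA quality, was 0.995 ± 0.028, 0.921 ± 0.038 and 0.947 ± 0.029 (SD, n = 3 each). Its exact p against untreated was 0.1 at 30 min and 0.2 at 120 min. The median log2 change of all tested probe sets was -0.037 at 30 min and -0.043 at 120 min.

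The first comparison asked which transcripts changed within 30 min of NECA. Nr4a1 (probe set 102371_at), an immediate early nuclear receptor gene, rose 14.5-fold, from a signal of 89.5 ± 8.25 to 1402 ± 83.7 (SD, n = 3 each). The cytokine gene Il6 (102218_at) rose from 2.21 ± 0.98 to 67.4 ± 25.4 (SD, n = 3 each), and Fos (160901_at), which encodes an AP-1 subunit, rose 2.68-fold from 287 ± 58.9 to 774 ± 68.4. The log2 changes of Nr4a1, Il6 and Fos were 3.86 ± 0.16, 2.85 ± 0.22 and 1.42 ± 0.15 (SE), with adjusted p-values of 2.03e-07, 0.000136 and 0.000916.

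The other 7 of the 10 largest rises at 30 min lay between 1.41 and 1.98 on the log2 scale. Nr4a2, a nuclear receptor of the Nr4a family, rose by 1.98 ± 0.17 (adjusted p = 0.000164), and its second probe set rose by 1.70. Sphk1, a kinase that makes sphingosine 1-phosphate, rose by 1.94 ± 0.22 (adjusted p = 0.00158), and the small GTPase gene Rab20 by 1.80 ± 0.21 (adjusted p = 0.00192). Ddit4, an inhibitor of mTOR signalling, rose by 1.65 ± 0.14 from an already high signal of 268 ± 36.2 (SD, n = 3). Bcl3, of the IkB family, rose by 1.63 ± 0.24, Rgs2, a regulator of G protein signalling, by 1.51 ± 0.20, and Ankrd33b by 1.41 ± 0.19. For these 10 genes the 3 treated arrays all lay above the 3 untreated arrays.

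The cAMP and CREB target genes rose as a list at 30 min, with 3 of 15 tested members up (Nr4a1, Nr4a2 and Rgs2), 0 down and 12 not passing. Adjusted over the list alone, 9 rose. The list's median log2 change was 0.59 (camera adjusted p = 2.64e-15, and adjusted p = 0.00273 with an estimated correlation). Without the genes that it shares with the immediate early list, its camera p was 4.85e-11. Per1, a clock gene that cAMP can induce, was at 0.70 ± 0.15 without passing (adjusted p = 0.129).

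Immediate early transcription factors also rose as a list, with a median of 0.35 (camera adjusted p = 1.18e-10, and adjusted p = 0.00373 with an estimated correlation). Of 19 tested members 5 rose, 0 fell and 14 did not pass, and 7 rose adjusted over the list alone. Beside Nr4a1 and Fos, the AP-1 gene Junb rose by 1.11 ± 0.17, Ier2 by 0.73 ± 0.13 and Atf3, a stress-induced transcription factor, by 0.69 ± 0.12. The call of Junb was lost without untreated replicate 1 or 2 or NECA 30 min replicate 3 (adjusted p up to 0.0976). The call of Ier2 was lost without any single array except NECA 30 min replicate 2 (up to 0.223), and that of Atf3 without any except that array and NECA 120 min replicate 1 (up to 0.232).

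MAP kinase phosphatases and feedback inhibitors rose as a list (median 0.25, camera adjusted p = 5.47e-05, and adjusted p = 0.0254 with an estimated correlation). Of its 12 members 2 rose, Rgs2 and the immediate early gene Ier3 (1.37 ± 0.12, adjusted p = 0.000164), 0 fell and 10 did not pass, while 5 rose adjusted over the list alone. The phosphatase gene Dusp1, at 0.45 ± 0.11, did not pass at 30 min (adjusted p = 0.286).

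For a further 3 lists the camera call at 30 min was lost with an estimated correlation. The estimates for the cytokine, glucocorticoid and clock lists were -0.054, -0.047 and -0.026. All lay below the preset of 0.01, so a higher correlation between members did not end these calls. Among 9 cytokines and chemokines 1 rose (Il6), 0 fell and 8 did not pass, with 2 up adjusted over the list alone (camera adjusted p = 0.00913, and adjusted p = 0.0862 with an estimated correlation). That call was also lost without NECA 30 min replicate 2 (adjusted p = 0.0901) and with no filter on low signals (adjusted p = 0.245). Among 13 glucocorticoid-responsive genes 1 rose and 12 did not pass, with 4 up adjusted over the list alone (camera adjusted p = 0.00581, and adjusted p = 0.0776 with an estimated correlation). The member that rose, the kinase gene Sgk1 (0.91 ± 0.13), lost its call without untreated replicate 2 or 3 (adjusted p up to 0.086). Among 14 circadian clock genes 1 rose, the transcriptional repressor gene Bhlhe40 (1.09 ± 0.14, adjusted p = 0.00386), and 13 did not pass, with 3 up adjusted over the list alone. That list's camera adjusted p was 0.0188, and adjusted p = 0.0953 with an estimated correlation, and its call was lost without untreated replicate 3 or NECA 30 min replicate 2 (adjusted p up to 0.15), and with a stricter filter (0.0577). The lists called at 30 min share genes, among them Dusp1, Per1, Rgs2 and Nfil3, so their calls are not independent. In the other 18 lists 3 further members rose, Bcl3 of the NF-kB list, Cebpd of the JAK-STAT list and Atf3 of the stress response list, and no camera call was made (adjusted p from 0.0542). The stress response list passed without untreated replicate 1 (0.0357) or NECA 30 min replicate 3 (0.0265), with the Gapdh 3' to 5' ratio as a covariate (0.0319) and by fry (0.0103), and the glycolysis list without NECA 30 min replicate 3 (0.00886) and with that covariate (0.0183). With an estimated correlation neither passed (adjusted p = 0.146 and 0.487). In all, 10 lists passed at 30 min with that covariate, against 6 without it. The markers of pituitary hormone cells had a median of -0.22 at 30 min without the covariate (camera adjusted p = 0.198). The call of Cebpd was lost without untreated replicate 2 (adjusted p = 0.0743). The JAK-STAT list had a median of -0.037, a mean of 0.10 and a camera direction of up (adjusted p = 0.198).

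At 30 min, 28 probe sets for 25 named genes were higher and 0 were lower by limma, with 19 of the 28 at least 2-fold. At an unadjusted p under 0.05, 304 were higher and 369 lower. The 28 all had non-overlapping groups of arrays, as did 6.11% of tested probe sets upward and 8.65% downward, where chance gives 10% over both directions. The negative changes with the smallest p did not pass: Ccn2, a matricellular growth regulator, was at -0.67 ± 0.14 (adjusted p = 0.104), Apoa5 at -1.43 ± 0.33, Taf1b at -0.88 ± 0.22, Ncbp2 at -0.52 ± 0.14 and Lmx1b at -1.20 ± 0.32. Without NECA 30 min replicate 2 the probe sets lower at 30 min numbered 46, Ccn2 among them (-0.80, adjusted p = 0.0222), and without untreated replicate 2 the probe sets higher numbered 15. With the Gapdh 3' to 5' ratio as a covariate, chosen after seeing the data, 4 probe sets stayed higher, for Nr4a1 (3.96), Il6 (2.98), Nr4a2 (2.13) and Ier3 (1.52), while Fos at 1.16 and Rgs2 at 1.71 did not pass (adjusted p = 0.19 and 0.141). The call of Rgs2 was also lost with only the compared groups in the fit (adjusted p = 0.0513).

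**Figure D1:**
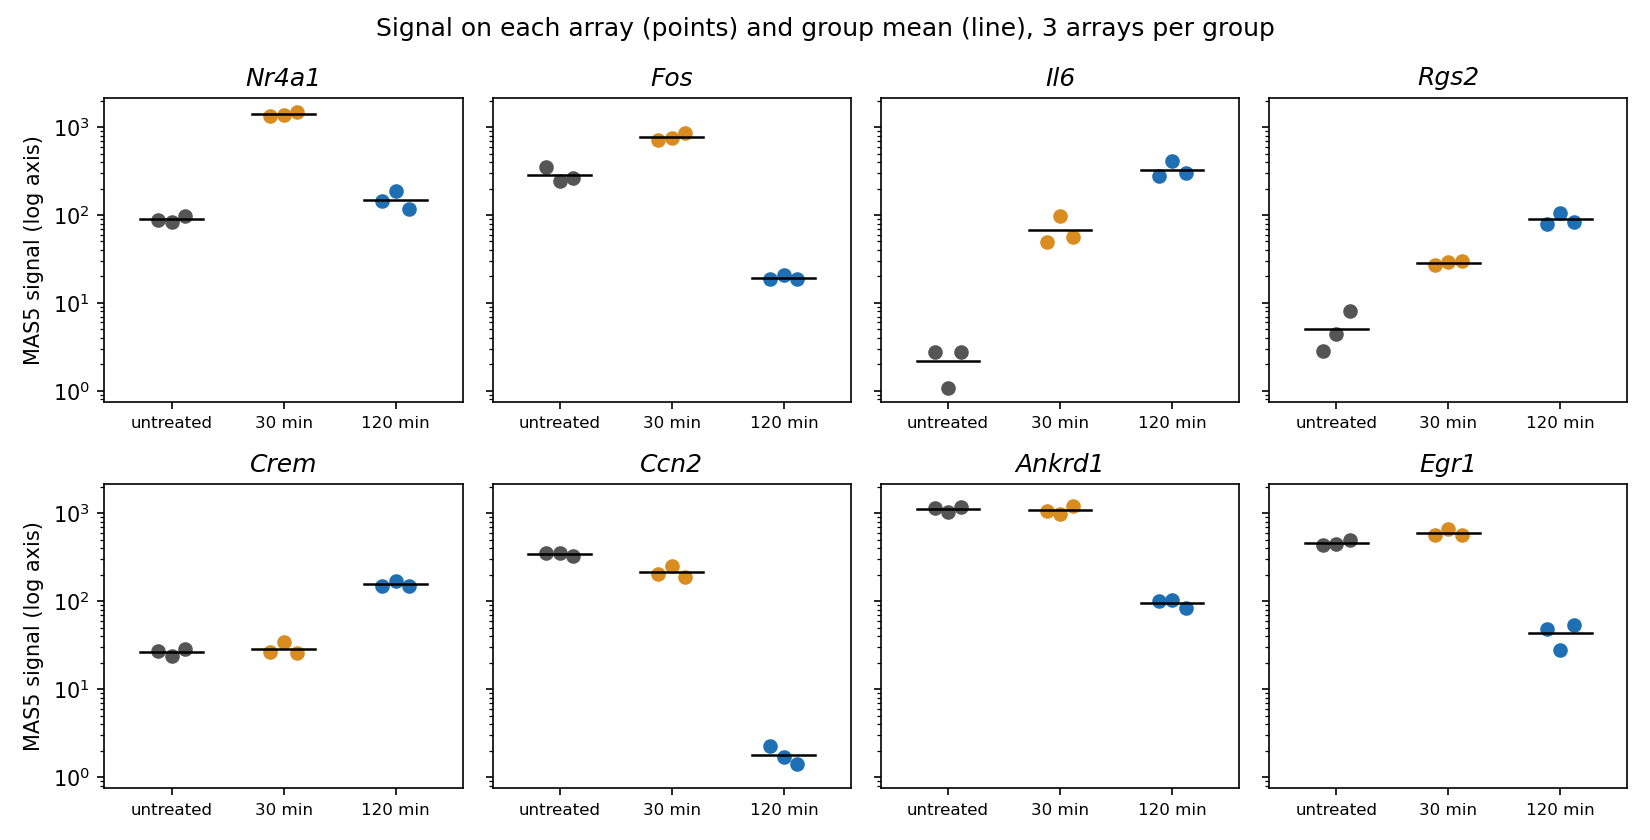
MAS5 signal (log axis) of 8 genes on each of the 9 arrays (points) with group means (lines), 3 arrays per group. Nr4a1 was at 1402 at 30 min against 89.5 untreated, and Ccn2 at 1.79 at 120 min against 344 untreated.

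The second comparison asked which transcripts differed after 120 min of NECA. Il6 reached a signal of 329 ± 68.6 from 2.21 ± 0.98 in untreated cells (SD, n = 3 each), 32.9-fold on the offset scale. Ccn2 (probe set 93294_at) and Ccn1, which encode related matricellular proteins, fell from 344 ± 13.3 to 1.79 ± 0.44 and from 369 ± 61.1 to 13.1 ± 6.89 (SD, n = 3 each). Fos, higher than untreated at 30 min, was 10.6-fold lower than untreated at 120 min. The log2 changes of Il6, Ccn2, Ccn1 and Fos were 5.04 ± 0.22, -5.18 ± 0.14, -4.20 ± 0.21 and -3.41 ± 0.15 (SE), with adjusted p-values of 1.16e-07, 1.3e-09, 2.66e-07 and 1.16e-07.

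Among the 10 largest rises at 120 min, Csf2rb, the shared beta chain of the GM-CSF receptor family, rose by 3.52 ± 0.22 and the vitamin D receptor gene Vdr by 3.46 ± 0.19, from a signal of 30.9 ± 6.95 to 415 ± 27.7 (SD, n = 3 each). Ramp3, a partner protein of the calcitonin receptor-like receptor, rose by 3.02 ± 0.27, and the atypical chemokine receptor gene Ackr3 by 2.61 ± 0.22. The others of the 10 were Bcl3 (3.20 ± 0.24), Rgs2 (2.92 ± 0.20), the deubiquitinase gene Usp2 (2.62 ± 0.29), Nfil3, a basic leucine zipper repressor (2.40 ± 0.16), and Srxn1, which repairs oxidised peroxiredoxins (2.27 ± 0.22). Second probe sets of Usp2 (0.11) and Srxn1 (-0.59, adjusted p = 0.183) did not pass, while those of Vdr (1.37) and Nfil3 (0.88) did. Adjusted p-values of these 10 rises ranged up to 0.000234.

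The 10 largest falls at 120 min included Ankrd1, a nuclear ankyrin repeat protein gene, which fell by 3.43 on the log2 scale (SE 0.13) from a signal of 1117 ± 75.8 (SD, n = 3). The zinc finger transcription factor genes Egr1 and Egr2 changed by -3.22 ± 0.19 and -2.68 ± 0.12. F3, which encodes tissue factor, changed by -2.90 ± 0.18, Ier2 by -2.52 ± 0.13, the angiomotin-like gene Amotl2 by -2.48 ± 0.14 and the antiproliferative gene Btg2 by -2.12 ± 0.12, all past the test. All 3 treated arrays lay below all 3 untreated arrays for each of the 10.

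Immediate early transcription factors fell as a list at 120 min, with a median log2 change of -0.56 (camera adjusted p = 2.54e-05, and adjusted p = 0.0253 with an estimated correlation). Of 19 members 8 fell, 2 rose and 9 did not pass, and adjusted over the list alone 10 fell and 5 rose. Beside Fos, Egr1, Egr2, Ier2 and Btg2, the falls were in Junb, Klf6 and Myc. The rises were in Nfil3 and Nr4a1, the latter at 0.67 ± 0.16 (adjusted p = 0.0423). The call of Nr4a1 at 120 min was lost without any 1 of 6 arrays, the 3 untreated, NECA 30 min replicate 1 and NECA 120 min replicates 1 and 2 (adjusted p up to 0.184).

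SRF targets and actin cytoskeleton genes fell as a list (median -0.34, camera adjusted p = 2.44e-05, and adjusted p = 0.0253 with an estimated correlation). Of 17 members 4 fell, 0 rose and 13 did not pass, while 8 fell adjusted over the list alone. The falls were in Ccn2, Ankrd1, Ccn1 and the small GTPase gene Rhob (-0.90 ± 0.17, adjusted p = 0.0109), whose call was lost without untreated replicate 1 (adjusted p = 0.0671). Growth and angiogenic factors, which share Ccn1 and Ccn2, had 3 of 16 members down, 1 up and 12 not passing, with 4 down and 1 up adjusted over the list alone. Their camera adjusted p was 0.00849, and adjusted p = 0.204 with an estimated correlation, and the call was lost with no filter on low signals (adjusted p = 0.42). Within that list Hbegf, an EGF receptor ligand, fell (-1.04 ± 0.13) and Vegfa, the vascular endothelial growth factor gene, rose 2.19-fold (1.13 ± 0.20, adjusted p = 0.00599). Bmp4 of that list was at -0.49 without passing (adjusted p = 0.172), while its second probe set was at -1.89 (adjusted p = 0.000889). Vegfa stood at 0.58 ± 0.20 at 30 min without passing (adjusted p = 0.531), and with the Gapdh 3' to 5' ratio as a covariate its change at 120 min was 0.93 (adjusted p = 0.0857).

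The cAMP and CREB target genes moved both ways at 120 min, with 9 of 15 up, 4 down and 2 not passing, and 9 up and 5 down adjusted over the list alone. The median was 0.92 (camera adjusted p = 0.000932, and adjusted p = 0.0544 with an estimated correlation). Crem, which encodes a cAMP response element modulator, rose by 2.26 ± 0.15 (adjusted p = 1.9e-06) and its second probe set by 2.46. Dusp1 and Per1, which cAMP can induce through CREB, fell, Dusp1 with a log2 change of -2.07 ± 0.11 and Per1 with an adjusted p of 0.0025. The MAP kinase feedback list held 3 rises, 2 falls and 7 members that did not pass, with 3 up and 3 down adjusted over the list alone (camera adjusted p = 0.597). In it Rgs2 rose, Ier3 rose by 0.82 ± 0.12, and Dusp1 and Zfp36 fell, Zfp36 at -0.98 ± 0.15.

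JAK-STAT signalling and feedback genes had 4 of 16 up, 3 down and 9 not passing, with 6 up and 3 down adjusted over the list alone (median 0.15, camera adjusted p = 0.0132, and adjusted p = 0.182 with an estimated correlation). Socs3, a feedback inhibitor of cytokine signalling, rose by 2.11 ± 0.15 and its second probe set by 3.69, Cebpd rose by 2.12 ± 0.14 and Cebpb by 1.11 ± 0.14, while the kinase gene Pim1 fell (-0.76 ± 0.13). Among 9 cytokines and chemokines Il6 rose, Cxcl5 fell (-0.85 ± 0.17) and 7 did not pass, the same numbers as adjusted over the list alone. That list's median was -0.23 and its mean 0.37, its camera direction was down (adjusted p = 0.929) and fry's was up (adjusted p = 0.00594). Among 13 NF-kB target and feedback genes 1 rose (Bcl3) and 12 did not pass, also adjusted over the list alone (camera adjusted p = 0.0992).

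Unfolded protein and integrated stress response genes fell as a list (median -0.31, camera adjusted p = 0.0132, and adjusted p = 0.0994 with an estimated correlation). Here too the estimate, -0.018, lay below the preset of 0.01. Of 14 members 5 fell, 1 rose and 8 did not pass, with 6 down and 1 up adjusted over the list alone. Gadd45a, a growth arrest gene, changed by -1.79 ± 0.13, Herpud1, of the degradation pathway of the endoplasmic reticulum, by -1.21 ± 0.14, and the pseudokinase gene Trib3 by -1.24 ± 0.14, all past the test. Without NECA 120 min replicate 1 the list's call was lost (adjusted p = 0.0558). Cholesterol synthesis and uptake genes rose as a list (median 0.43, camera adjusted p = 9.98e-05, and adjusted p = 0.071 with an estimated correlation). Of their 12 members 1 rose, Hmgcs1 of the sterol pathway (0.86 ± 0.18), and 11 did not pass, with 3 up adjusted over the list alone.

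Other lists held single changes at 120 min without a camera call. The oxidative stress and DNA damage list had 5 of 16 up, 3 down and 8 not passing, also adjusted over the list alone (camera adjusted p = 0.239). Its rises included Gclc and Hmox1, of glutathione synthesis and heme breakdown, at 1.39 ± 0.13 and 1.21 ± 0.14. Glucocorticoid-responsive genes had 3 of 13 up, 4 down and 6 not passing, also adjusted over the list alone (camera adjusted p = 0.287), with Sgk1 at -1.20 ± 0.13. Circadian clock genes had 3 of 14 up (Nfil3, Cry1 at 1.06 ± 0.15 and Arntl at 0.99 ± 0.15), 2 down and 9 not passing, and 4 up and 4 down adjusted over the list alone (camera adjusted p = 0.384). Among 10 heat shock proteins 2 rose, among them the co-chaperone gene Bag3 (1.43 ± 0.14), and 8 did not pass, also adjusted over the list alone (camera adjusted p = 0.0519). That list passed without untreated replicate 1, NECA 30 min replicate 2 or NECA 120 min replicate 3 (adjusted p from 0.0248), and by fry (0.00594), and not with an estimated correlation (adjusted p = 0.185). The call of its other rise, Hsph1 (0.99 ± 0.21), was lost without untreated replicate 1 or 2 or NECA 120 min replicate 3 (adjusted p up to 0.106). Among 18 glycolysis and hypoxia genes 2 rose, Vegfa and the hexokinase gene Hk2 (1.81 ± 0.15), 1 fell (Adm, at -0.81 ± 0.16) and 15 did not pass, with 3 up and 1 down adjusted over the list alone (camera adjusted p = 0.071). The glycolysis list passed without NECA 120 min replicate 1 (adjusted p = 0.027), with only the compared groups in the fit (0.0454) and with the Gapdh 3' to 5' ratio as a covariate (0.0377), and not with an estimated correlation (adjusted p = 0.385).

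Among 20 extracellular matrix and protease genes 2 rose, Ptx3 (1.04 ± 0.20) and Has2 (0.80 ± 0.19), and 18 did not pass, with 2 up and 1 down adjusted over the list alone (camera adjusted p = 0.775). Of 6 prostaglandin and nitric oxide synthesis genes the cyclooxygenase gene Ptgs2 rose (0.92 ± 0.20), the prostaglandin receptor gene Ptger4 fell (-1.32 ± 0.26) and 4 did not pass, also adjusted over the list alone (camera adjusted p = 0.774). Several of these calls were lost without single arrays, with the number of such arrays of 9 and the highest adjusted p as follows. They were 6 for Has2 (0.173 without NECA 120 min replicate 3), 6 for Ptgs2 (0.0914 without untreated replicate 3), 5 for Hmgcs1 (0.107 without untreated replicate 2) and 4 for Adm (0.0716 without untreated replicate 2). They were 3 for Cxcl5 (0.0846 without untreated replicate 1) and 2 for Ptger4 (0.0861 without untreated replicate 1). Members counted above but not named had such limits too. They were 7 for Stat3 of the JAK-STAT list (up to 0.143), 6 for Txnrd1 of the oxidative stress list (0.187) and 5 for Ddit3 of the stress response list (0.0974). Of the glucocorticoid list they were 3 for Klf9 (0.0912) and 1 for Errfi1 (0.0664). The second probe set of Stat3 rose by 0.88 (adjusted p = 0.00416).

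Folliculostellate markers and gap junction genes had 0 of 10 members past the test at either time, with 1 up at 120 min adjusted over the list alone (camera adjusted p = 0.572 at 30 min and 0.312 at 120 min). The connexin gene Gja1 was at 0.16 ± 0.15 at 30 min (adjusted p = 0.713) and 0.61 ± 0.15 at 120 min (adjusted p = 0.0527, and 0.0448 with a stricter filter). Adenosine receptors and adenosine metabolism had 0 of 8 past the test at both times, with 1 up at 30 min adjusted over the list alone (camera adjusted p = 0.935 and 0.374), and the receptor gene Adora2b was not past the signal filter and is not analysed here. Cyclins and cell cycle genes had 0 of 24 past the test at both times (camera adjusted p = 0.426 and 0.929), cytosolic ribosomal proteins 0 of 14 (0.61 and 0.0643) and the mitochondrial respiratory chain 0 of 29 (0.22 and 0.0519), also adjusted over the list alone. At 120 min the mitochondrial list passed camera without untreated replicate 3, NECA 30 min replicate 2 or 3, or NECA 120 min replicate 1 or 3 (adjusted p from 0.023), with only the compared groups in the fit (0.0231) and with a stricter filter (0.0442), and not with an estimated correlation (adjusted p = 0.385). The ribosomal list passed without untreated replicate 2, NECA 30 min replicate 2 or NECA 120 min replicate 1 (adjusted p from 0.017), with only the compared groups (0.0454) and with the Gapdh 3' to 5' ratio as a covariate (0.0173), and not with an estimated correlation (adjusted p = 0.406). Of 8 tested markers of pituitary hormone cells 1 rose at 120 min, the transcription factor gene Pitx1 (1.08 ± 0.12, adjusted p = 0.000266), and 7 did not pass, also adjusted over the list alone (camera adjusted p = 0.666). Of 9 tested macrophage and leukocyte markers 0 passed at either time, with 1 up at 120 min adjusted over the list alone (camera adjusted p = 0.44 and 0.77). Over all arrays the mean signals of the 18 such markers on the array ran from 1.60 to 443 with a median of 13.5, and those of Cd14, Cd68, Adgre1 and Ptprc were 443, 430, 5.62 and 2.90. The 15 hormone cell markers on the array had a median of 26.1, with 77.7 for Gh, 43.2 for Prl and 26.1 for Pomc. Only 2 of 11 endothelial markers were tested, Eng and Pecam1, with mean signals of 589 and 22.2 against a median of 6.64 for the 11, so that list had no set test.

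At 120 min, 144 probe sets for 120 named genes were higher and 121 for 110 named genes were lower, 75 and 60 of them at least 2-fold. All had non-overlapping groups of arrays, as did 12.3% of tested probe sets upward and 13% downward, where chance gives 10% over both directions. Without untreated replicate 2 the numbers were 88 higher and 70 lower, without NECA 120 min replicate 3 they were 95 and 79, and without untreated replicate 1 there were 60 lower. With the Gapdh 3' to 5' ratio as a covariate, 87 were higher and 64 lower, and 135 of the 265 calls were kept. The calls of Rhob, Hmgcs1, Ptx3, Has2, Ptgs2, Ptger4, Adm, Cxcl5 and Nr4a1 were lost with it, and those of the JAK-STAT and stress response lists (adjusted p = 0.0512 for both). The sizes with it were smaller for Hmgcs1 (0.64), Ptx3 (0.87), Ptgs2 (0.85) and Has2 (0.80), and larger for Rhob (-0.92), Ptger4 (-1.36), Adm (-0.89), Cxcl5 (-0.94) and Nr4a1 (0.74). The median of the JAK-STAT list was 0.20 and that of the stress response list -0.35. The median standard error rose from 0.18 to 0.22, and the 130 lost calls had median sizes of 0.82 without and 0.79 with the covariate.

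**Figure D2:**
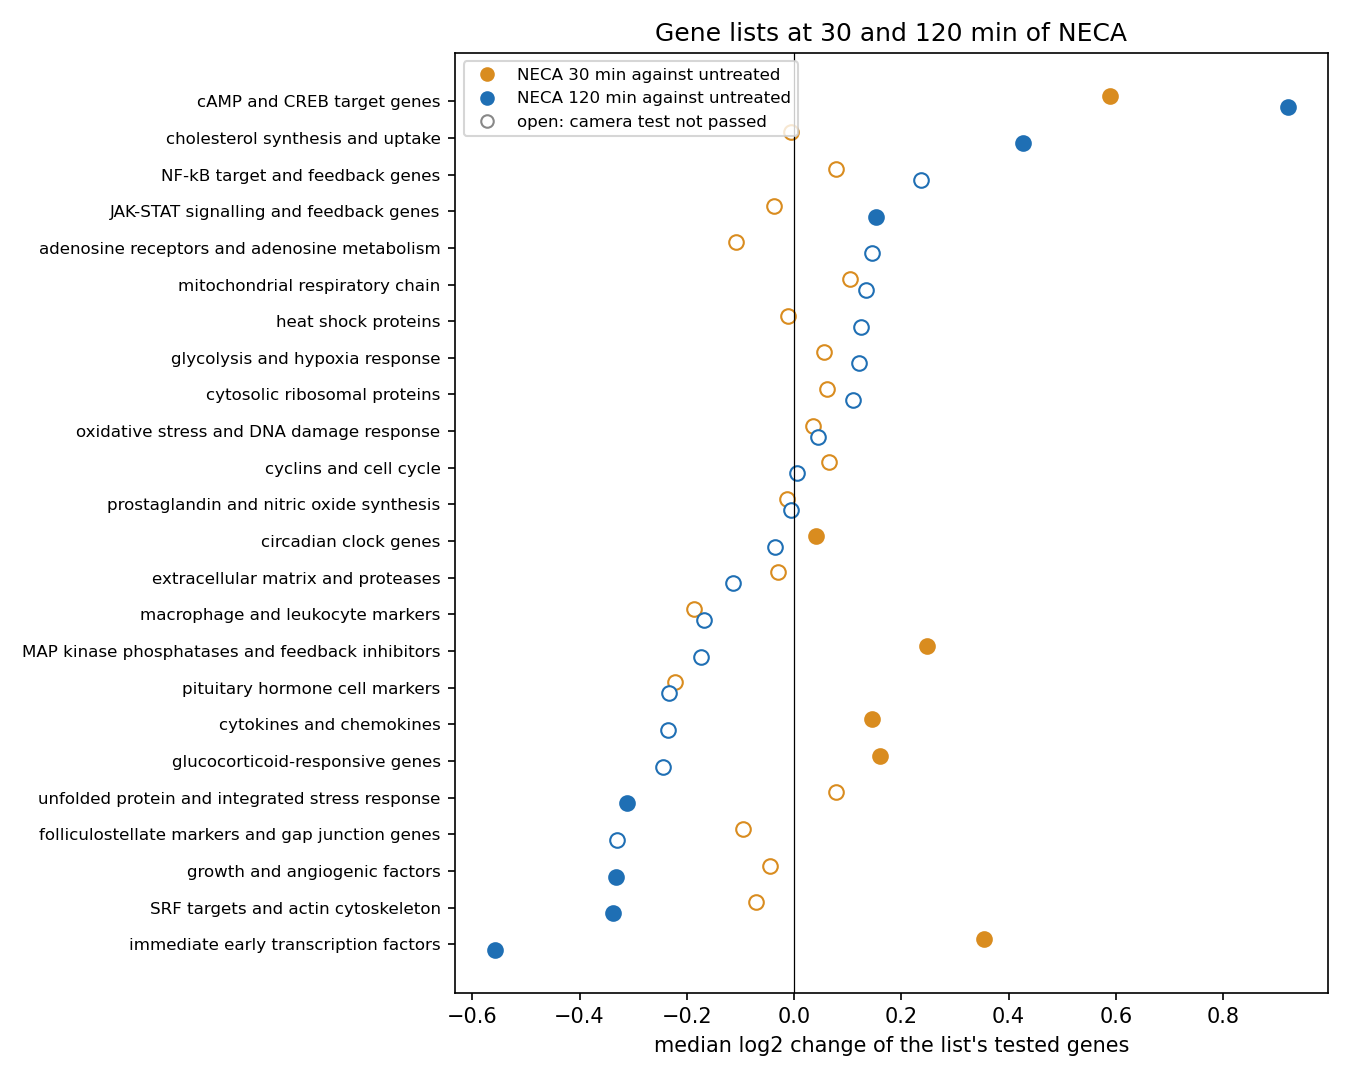
Median log2 change of the tested genes of 24 gene lists (rows) at 30 min (orange) and 120 min (blue) of NECA against untreated cells, filled where the camera test passed with its preset correlation. The cAMP and CREB list was at 0.59 and 0.92, and the immediate early list at 0.35 and -0.56.

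The third comparison tested the difference between 120 and 30 min of NECA directly. From 30 to 120 min Fos changed by -4.83 ± 0.15, Ccn2 by -4.51 ± 0.14 and Ccn1 by -4.48 ± 0.21 on the log2 scale (SE). Nr4a1 fell by 3.18 (SE 0.16), from a signal of 1402 ± 83.7 to 149 ± 34.5 (SD, n = 3 each). Egr1 was at -3.60 ± 0.19 and Ankrd1 at -3.38 ± 0.13. Csf2rb rose by 3.58 ± 0.22, Vdr by 3.53 ± 0.19, Ramp3 by 2.39 ± 0.27, Il6 by 2.19 ± 0.22 and Crem by 2.18 ± 0.15. Adjusted p-values of these genes ranged from 4.23e-09 to 0.000265.

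Immediate early transcription factors had 10 of 19 members lower at 120 than at 30 min, 1 higher and 8 not passing, with 12 and 2 adjusted over the list alone (median -0.94, camera adjusted p = 3.13e-15, and adjusted p = 0.00251 with an estimated correlation). Ier2 (-3.26 ± 0.13), Egr2 (-2.79 ± 0.12) and Btg2 (-2.43 ± 0.12) were among them. MAP kinase feedback genes had 3 of 12 lower, 1 higher and 8 not passing, with 5 and 1 adjusted over the list alone (camera adjusted p = 0.00202, and adjusted p = 0.0475 with an estimated correlation), Dusp1 at -2.51 ± 0.11. Unfolded protein and integrated stress response genes had 7 of 14 lower and 7 not passing, with 8 lower and 1 higher adjusted over the list alone (camera adjusted p = 4.74e-05, and adjusted p = 0.0252 with an estimated correlation). SRF targets and actin genes had 4 of 17 lower and 13 not passing, with 5 lower adjusted over the list alone (camera adjusted p = 3.71e-05, and adjusted p = 0.0252 with an estimated correlation). Without Ccn1, Ccn2 and Ankrd1 that list's camera p between the times was 0.14 (p = 0.168 with an estimated correlation), with a median of -0.011. Cholesterol genes were higher as a list, with 1 of 12 members past the test, 11 not passing and 3 higher adjusted over the list alone (camera adjusted p = 3.3e-05, and adjusted p = 0.0475 with an estimated correlation). The member past the test was Sqle (0.44 ± 0.10, adjusted p = 0.0364). Its call was lost without any single array except NECA 30 min replicate 2 (adjusted p up to 0.155), with quantile normalization (0.0917) and with no filter (0.112).

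For a further 3 lists the call between the times was lost with an estimated correlation. The estimates for the JAK-STAT and growth lists, 0.035 and 0.085, lay above the preset of 0.01. That for the glucocorticoid list, -0.047, lay below it, so a higher correlation between members did not end that call. JAK-STAT genes had 3 of 16 higher, 1 lower and 12 not passing, with 9 and 4 adjusted over the list alone (camera adjusted p = 0.0239, and adjusted p = 0.196 with an estimated correlation), with Socs3 at 1.62 ± 0.15 and Pim1 at -1.20 ± 0.13. Growth and angiogenic factors had 3 of 16 lower and 13 not passing, with 4 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0116, adjusted p = 0.235 with an estimated correlation, and 0.505 with no filter). Glucocorticoid-responsive genes had 3 of 13 lower, Dusp1, Sgk1 (-2.12 ± 0.13) and Per1 (-1.70 ± 0.15), and 10 not passing, with 4 lower and 1 higher adjusted over the list alone. That list had a median of 0.0051, a mean of -0.46 and a camera direction of down (adjusted p = 0.0387, and adjusted p = 0.156 with an estimated correlation). The calls of the JAK-STAT and glucocorticoid lists were also lost without NECA 30 min replicate 2 (adjusted p = 0.084 for both), the former without NECA 120 min replicate 3 and the latter without NECA 120 min replicate 1 (0.0875). The cAMP list had 5 of 15 higher, 7 lower and 3 not passing, with 6 higher and 7 lower adjusted over the list alone (median 0.022, mean -0.21, camera direction down, adjusted p = 0.431).

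From 30 to 120 min, 106 probe sets for 89 named genes rose and 127 for 111 named genes fell. Without NECA 30 min replicate 2 the rises numbered 177, and without NECA 120 min replicate 2 or 3 they numbered 64 or 65. The F-test over the 3 groups passed for 243 probe sets, 381 without NECA 30 min replicate 2 and 159 without NECA 120 min replicate 3. By classes set before the data were examined, which overlap, 17 probe sets rose at 30 min and fell again by 120 min, among them those of Nr4a1, Nr4a2, Fos and Ankrd33b. A late rise was found for 88 probe sets, with Csf2rb, Vdr, Ramp3 and Crem, and a late fall for 86, with Ccn2, Ccn1, Ankrd1 and Egr1. Il6, Bcl3, Rgs2 and Sphk1 were among 13 probe sets higher than untreated at both times. Of these 13, 6 also counted as a late rise, Il6, Bcl3 and Rgs2 among them, and 4 as an early rise that fell again, Nr4a1 and Nr4a2 among them. The second probe set of Nr4a2 did not pass at 120 min against untreated (0.53, adjusted p = 0.109). Probe sets of Fos, Ier2, Junb and Sgk1 were higher than untreated at 30 min and lower at 120 min, 5 in all, which also counted as an early rise that fell again and as a late fall, with the limits given above for the last 3 genes at 30 min.

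The log2 changes at 30 and 120 min had a correlation across probe sets of 0.44, where simulated unchanged groups that share the 3 untreated arrays gave 0.50. Their covariance was 0.0478 against a simulated 0.0214. The overlap of probe sets higher at both times was 13, where independent lists would share 0.514. Simulated unchanged groups shared 0, but groups without changes give few calls at all. That value therefore does not show how much the shared controls add to the overlap. Higher at 30 min and lower at 120 min were 5, where independent lists would share 0.432. Because 3 untreated arrays cannot be split into separate sets of 2, part of any excess in the overlaps may come from the shared controls. The simulated covariance was drawn with the shared controls included.

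**Figure D3:**
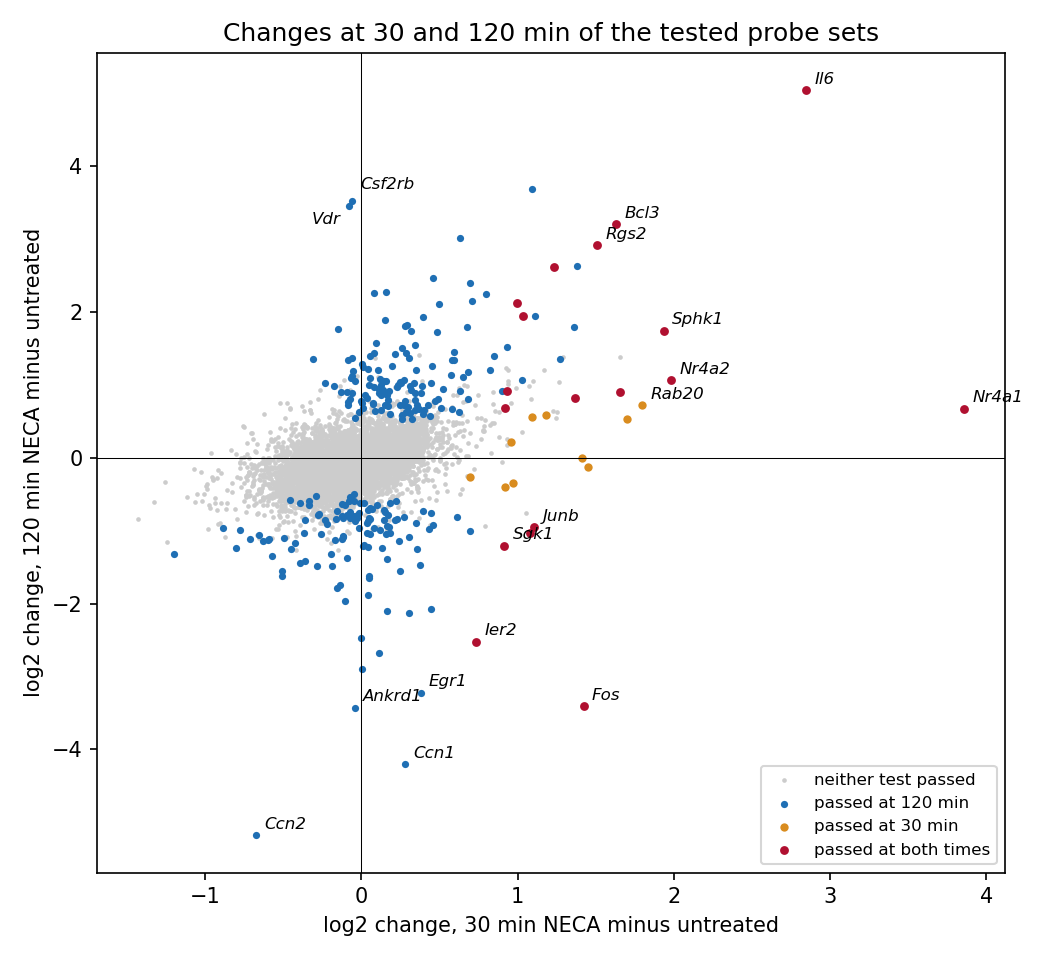
Log2 change at 30 min (x axis) and 120 min (y axis) of NECA against untreated cells for the 7851 tested probe sets, coloured by the comparison in which the test passed. Il6 stood at 2.85 and 5.04, Nr4a1 at 3.86 and 0.67, Fos at 1.42 and -3.41, and Ccn2 at -0.67 and -5.18.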

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

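The tests of a raised level in the untreated cells, of RNA quality as the whole cause and of the spread of a single array were chosen only after the results were seen. The values in this part drew attention because the change against untreated cells differed between 30 and 120 min in a direct test of the difference. That test passed for 106 probe sets that were higher and 127 that were lower at 120 min.

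Among the genes named for the largest changes, those higher at 120 than at 30 min were Csf2rb (log2 difference 3.58), Vdr (3.53), Ramp3 (2.39), Il6 (2.19), Crem (2.18), Srxn1 (2.12), Nfil3 (1.71), Bcl3 (1.57), Rgs2 (1.41), Ackr3 (1.38) and Usp2 (1.25). The difference of Usp2 did not pass without any single array of the 2 NECA groups (adjusted p up to 0.149, without NECA 120 min replicate 3). It also did not pass with quantile normalization (0.0568), no offset (0.0977), no filter (0.108), no intensity trend (0.0643) or the Gapdh 3' to 5' ratio as a covariate (0.127), and the second probe set of Usp2 differed by 0.018 (adjusted p = 0.979). The second probe set of Srxn1 differed the other way, by -0.34, without passing (adjusted p = 0.536). The difference of Ackr3 did not pass with no offset (0.149). Those lower were Fos (-4.83), Ccn2 (-4.51), Ccn1 (-4.48), Egr1 (-3.60), Ankrd1 (-3.38), Ier2 (-3.26), Nr4a1 (-3.18), F3 (-2.90), Egr2 (-2.79), Amotl2 (-2.47), Btg2 (-2.43), Ankrd33b (-1.41), Rab20 (-1.07), Nr4a2 (-0.92) and Ddit4 (-0.75). The difference of Rab20 did not pass without NECA 120 min replicate 2 or 3 (adjusted p up to 0.077), and that of Ddit4 without NECA 120 min replicate 1 or 2 (up to 0.0713).

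Among gene lists, immediate early transcription factors had a median log2 difference between the times of -0.94, the unfolded protein and integrated stress response -0.59, MAP kinase feedback genes -0.37, SRF targets and actin genes -0.23, and growth and angiogenic factors -0.11. The medians of the cholesterol and JAK-STAT lists were 0.48 and 0.43. The median of the glucocorticoid-responsive genes was 0.0051, against a mean of -0.46. The limits of the growth, JAK-STAT and glucocorticoid calls are those given with the comparison of the 2 times.

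Of 19 immediate early genes 8 fell below their untreated level at 120 min, 2 rose (Nfil3 and Nr4a1) and 9 did not pass, with a median log2 change of -0.56 over all 19 and -2.32 over the 8 that fell. The scaling of the arrays is argued against, since the median change of all tested probe sets was -0.043 and that of the 8 members was -2.33 with quantile normalization. RNA quality as the whole cause is argued against, as far as the Gapdh 3' to 5' ratio measures it: with that ratio as a covariate, which moved the tested probe sets by a median of 0.10, the median of the 8 was -2.30 and the 95% intervals of all 8 lay below 0. A contribution of RNA quality stays open, since 6 of the 8 passed with the covariate. Junb went from -0.95 ± 0.17 to -0.95 ± 0.22 (SE) (unadjusted p = 0.00136), where the larger error and the smaller number of calls ended its call. Klf6 went from -1.35 ± 0.24 to -1.02 ± 0.26. The covariate varies with the groups, so it may also take up a part of an effect of NECA. A lost call is therefore not by itself a sign of RNA quality. A raised level in the untreated cells also stays open and could not be tested, because 0 untreated arrays have a named time of 120 min, so a fall after handling or a change of medium may contribute and cannot be told apart from an effect of NECA.

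At 30 min 0 probe sets were lower by limma, against 28 higher and 369 lower at an unadjusted p under 0.05. The scaling of the arrays is argued against, since quantile normalization also gave 0 lower, with 29 higher. Slow decay of existing RNA may limit falls within 30 min and stays open. The test took the 110 probe sets that were lower at 120 than at 30 min and not called higher at 30 min. Their median change at 30 min was 0.15, with 28 of them below 0. That choice, by a low value at 120 against 30 min, favours high values at 30 min. A median above 0 therefore does not count against slow decay. The 121 probe sets lower at 120 min than untreated had a median change at 30 min of -0.013. That choice leans the other way, on high untreated values, and so favours low changes at 30 min. As a set these probe sets therefore showed little of their fall by 30 min. The spread of a single array goes with the pattern, since without NECA 30 min replicate 2 the number lower was 46, among them Matr3 (-1.76), U2surp (-1.76) and Cbx5 (-1.52), with 4 of the 46 lower at 120 min. All 28 probe sets higher at 30 min were also called without that array.

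For 30 min against untreated, 2 of the 10 splits of the 6 arrays gave as many calls as the real 28, and the highest other gave 55, with 0 of the real calls among them. The split with 55 put NECA 30 min replicate 2 with untreated replicates 1 and 2, which points to a structure of the samples that the groups do not hold. The real split was the only 1 of 10 with as many calls for 120 min against untreated (265, highest other 0) and for 120 against 30 min (233, highest other 0). Splits of 6 arrays are too few for a share under 0.05. Of 100 splits of the 9 arrays into 3 groups, the real split among them, only the real split gave as many as 243 calls by the F-test. Chance is therefore unlikely for that count over the 3 groups, which does not bear on the 30 min calls alone. The highest other split gave 186, kept the 3 arrays of NECA 120 min together and shared 175 calls with the real groups.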

How the results depend on the processing

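The covariate and the fit with plainly named probe sets were chosen after seeing the data, and the causes of the changes below were not tested unless stated. No called gene turned its direction. Over all genes named and all alternatives that keep the 9 arrays, a called gene passed in 1735 fits and did not in 92, and with 1 array left out in 1375 and 146. For called lists the numbers were 256 and 19, and 181 and 8. Uncalled lists passed in their main direction in 20 fits with the 9 arrays and in 17 with 1 left out. In 1 further fit with the 9 arrays an uncalled list passed in the opposite direction. With quantile normalization 28 of the 28 calls at 30 min, 244 of 265 at 120 min and 218 of 233 between the times were kept. Probe sets lower at 30 min numbered 2 with no filter, 1 with no intensity trend and 1 with only the compared groups in the fit. With the Gapdh 3' to 5' ratio as a covariate 4 were higher at 30 min, 87 higher and 64 lower at 120 min, 10 lists passed at 30 min and the correlation of the changes at both times was 0.617. The covariate varies with the groups and raised the median standard error from 0.18 to 0.27 at 30 min and 0.22 at 120 min, so part of the loss is by construction. The 24 calls lost at 30 min had a median size of 1.10 both without and with it, 6 of them at least as large and 18 smaller. The 130 lost at 120 min had median sizes of 0.82 and 0.79. With an estimated correlation 3, 2 and 5 lists passed at 30 min, at 120 min and between the times, and 13 at 120 min with fry. By fry the cytokines at 120 min were up, against camera's direction, at the same median of -0.23. Over probe sets past the F-test the correlation was 0.339.

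With 1 array left out, the probe sets higher at 30 min numbered 15 (without untreated replicate 2) to 39, and those lower 0 to 46 (without NECA 30 min replicate 2). At 120 min 88 (without untreated replicate 2) to 182 were higher and 60 (without untreated replicate 1) to 135 lower. Between the times 64 (without NECA 120 min replicate 2) to 177 (without NECA 30 min replicate 2) were higher, and the F-test passed for 159 (without NECA 120 min replicate 3) to 381 (without NECA 30 min replicate 2). The correlation of the changes lay between 0.357 and 0.539. The replicate numbers did not pair the arrays: of 9 pairs with the same number 1 had a correlation of residuals over 0.1, and the own number was best in 2 of 18. With the replicate block 27 were higher at 30 min, 136 higher and 111 lower at 120 min, and the call of the glucocorticoid list between the times was lost (adjusted p = 0.0514). Signals near the offset of 7.93, such as Ccn2 at 1.79 at 120 min, are known only as low, so their folds are limited by the background.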

Other observations

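The genes in this part were chosen after their values were seen, except those tested as a list of TEAD and YAP targets. The SRF test without 3 genes and the TEAD and YAP test without Nt5e were also chosen only after the results were seen. At 120 min, genes outside the fixed lists were among those higher than in untreated cells. Ugdh, which makes the UDP-glucuronate used for hyaluronan, rose by 0.74 ± 0.11 on the log2 scale (SE, adjusted p = 0.00241). Gfpt2, of the entry into the hexosamine pathway, rose by 1.42 ± 0.17 (adjusted p = 0.000402), and Uap1, which makes UDP-N-acetylglucosamine, by 1.73 ± 0.26 (adjusted p = 0.00253). Vcan, which encodes the hyaluronan-binding proteoglycan versican, rose by 1.77 ± 0.26, from a signal of 54.7 ± 22.2 to 195 ± 16.7 (SD, n = 3 each). These genes form no list fixed beforehand, and no enrichment was tested.

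Other rises at 120 min were in Dgat1, of triglyceride synthesis (2.24 ± 0.16), Procr, the endothelial protein C receptor gene (2.15 ± 0.15), Nfatc1, a calcium-regulated transcription factor (1.93 ± 0.23), and Nrp1, a coreceptor for semaphorins and VEGF (1.58 ± 0.13). Csf2rb2, a close relative of Csf2rb, rose by 1.36 ± 0.25, and Odc1, of polyamine synthesis, rose at both times (1.03 ± 0.12 and 1.95 ± 0.12). Falls at 120 min included Cdkn2b, an inhibitor of cyclin-dependent kinases (-1.63 ± 0.13), Ccng2, an unconventional cyclin linked to growth arrest (-1.56 ± 0.15), and Snai2, a zinc finger repressor (-1.23 ± 0.16). Txnip, an inhibitor of thioredoxin, and Zfp36l2, an RNA-binding protein gene, were at -1.62 ± 0.17 and -1.74 ± 0.24, while their second probe sets, at -0.22 and -0.26, did not pass. Adjusted p-values of those that passed ranged up to 0.0085.

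Ccn2, Ccn1, Ankrd1, Amotl2 and F3, among the largest falls at 120 min, are known as targets of the TEAD and YAP transcription factors, so the hypothesis was that other targets fell too. Of 5 tested members of a list of such targets whose values had not been examined before (Asap1, Dock5, Lats2, Ccdc80 and Ptpn14), 5 lay below 0 at 120 min and 0 passed on their own, with a median log2 change of -0.22 and a camera p of 0.0422 (0.0448 with Nt5e, whose values had been examined in another list). The p was 0.0836 with an estimated correlation. The same members gave a camera p of 0.866 at 30 min and 0.0721 for 120 against 30 min (0.193 with Nt5e). Between the times 4 of 5 lay below 0, and 1 passed on its own as lower. A lower activity of TEAD and YAP may account for part of the falls, as a hypothesis found and tested on the same arrays and not borne out by every test of it. For these genes too, a fall after handling or a change of medium may contribute. It cannot be told apart from an effect of NECA without untreated arrays of a named time. SRF targets remain as an alternative, since the SRF and actin list without Ccn1, Ccn2 and Ankrd1 gave a camera p of 0.0401 at 120 min, and 0.0718 with an estimated correlation, though 0.14 for 120 against 30 min, and 0.168 with an estimated correlation.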
